A study of Mus musculus with 8 samples.

How the data were processed

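RNA from sorted striatal medium spiny neurons (MSNs, the GABA-releasing projection neurons of the striatum) of male mice aged 4 weeks was measured on mouse Agilent arrays with 1 dye (Cy3). Per the labels, 4 arrays hold MSNs of R6/2;Scn4b-Venus mice and 4 hold MSNs of WT;Scn4b-Venus mice, here called control, with 1 mouse genotype per array and no other factor. R6/2 mice carry a transgene with exon 1 of human HTT and an expanded CAG repeat, and Venus is a fluorescent protein reporting Scn4b. Per the labels' protocols, cells positive for Venus and negative for propidium iodide were sorted, nanogram amounts of total RNA were extracted with a micro column kit, and labelling followed the Agilent standard protocol.

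Per the file headers, each scanner file holds spot intensity values from Agilent Feature Extraction 10.7.3.1, with background subtraction by spatial detrending, multiplicative detrending and surrogate values for dim spots, and no scaling between arrays. The files also hold the mean and local background intensity of each spot and the software's quality marks. Probe coordinates are on mm9, per the file headers. The deposited whole-series table has 55680 probes with the authors' raw intensity values and their log2 values, which are the log2 of the raw value over the array's 75th percentile. Per the file headers, that table also gives the authors' p-value from an unpaired t-test, its Benjamini-Hochberg corrected p-value and an absolute fold change. The authors' log2 values were used only as an alternative and for a comparison of fold changes. In the scanner file of R6/2 replicate 3, 1 garbled line was left out, so that 62974 spots were read in place of 62976.

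For the main values, the processed intensity was taken to log2, spots marked as outliers were left out, spots of a probe were averaged, and the 75th percentile over the non-control probes of the array was subtracted. Of 55681 non-control probes, 41378 were well above background on at least 4 of the 8 arrays and were tested. Probe names were turned into current gene symbols through the accession given with each probe (26762 probes), the symbol (3819) or an older symbol (639), and 24461 probes kept the name in the file. The table used for the names belongs to the assembly GRCm38.p6, and none of its coordinates were used. A gene was represented by its tested probe with the highest mean level, which left 26915 genes and transcripts. Other tested probes of a gene could give a smaller difference of the same sign, which is printed for only some genes.

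Group differences are R6/2 minus control, fitted with limma 3.58.1 on R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Where no control array was well above background, the fold is given as a lower bound against the lowest signal called well above background on each array. Gene lists were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes, over the 37 lists with at least 5 tested genes. Camera with an estimated correlation and limma's fry were run beside it. Per-array list scores are the mean log2 level of a list's tested genes. Groups of single values were compared by exact permutation tests, two-sided, over the 70 assignments of 8 arrays into 4 and 4, whose smallest p-value is 0.0286. The lists and the rule for named genes, and the tests and alternatives other than those said to be chosen after, were fixed before the data were examined.

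The lists, written from general knowledge, were MSN identity, direct pathway (D1) MSN, indirect pathway (D2) MSN, genes reported lower in HD (Huntington's disease) model striatum, immediate early and activity genes, potassium channels, sodium and calcium channels, glutamate receptors and postsynaptic density, GABA receptors and GABA synthesis, cAMP and phosphodiesterase signalling, RGS and small G protein regulators, and neuropeptides and peptide receptors. Further lists were cholesterol synthesis, oxidative phosphorylation, glycolysis, chaperones and heat shock, unfolded protein response, proteasome, autophagy and lysosome, DNA mismatch and break repair, p53 targets and apoptosis, transcriptional and chromatin regulators linked to huntingtin, Polycomb-repressed developmental regulators, clustered protocadherins, cytosolic ribosomal proteins, interferon response, and nuclear-receptor and retinoid signalling. Marker lists covered astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, striatal interneuron, cortical glutamatergic neuron, progenitor and neuroblast, ependymal and choroid plexus, and erythrocyte. Named genes are those past the threshold with separate groups, and, where fewer than 5 passed in a direction, the 8 annotated genes with the smallest p-value in that direction. Up to 4 members of each gene list with the smallest p-value, Htt and Scn4b are named as well, and a few of these list members are left unnamed. Predicted or unnamed transcripts at an adjusted p under 0.1, members singled out for their sign, and genes near a named one were chosen after their values were seen.

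The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, every probe on its own, an intensity trend, array weights, a replicate block, the authors' values, the share of probes well above background as a covariate, other thresholds, and leaving out each array in turn. A block for slide or scan day was not run, because the second slide and the second scan day held 1 array. Precision is limited by the number of arrays: the median standard error of a log2 difference was 0.30. The fits were tested on simulated data for R6/2 against control, 4 arrays each, on 26873 genes. These had the real means, spreads shrunk as the fit shrinks them, and 200 changed genes in each of 10 simulations. Genes were drawn independently, while the estimated correlation within the real MSN identity list was 0.13. The simulated list calls thus do not show how often lists of correlated genes are called by chance. limma recovered 63.9% of genes changed by 2 log2 units and 3.5% of genes changed by 1 log2 unit, and 6.39% of its calls were not changed genes. A shift of -0.5 log2 units of the MSN identity list was called by camera in 10 of 10 simulations, with an estimated correlation in 10 and by fry in 10, and 1 of 280 unshifted lists was called. Figures were drawn with matplotlib 3.10.9.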

Results

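MSNs sorted from the striatum of R6/2 mice and of control mice, 4 arrays per genotype, were compared at 4 weeks of age. Probes well above background made up 50.1%, 76.2%, 67.8% and 72.2% of all probes in control replicates 1 to 4 and 74.0%, 75.9%, 75.4% and 78.8% in R6/2 replicates 1 to 4. The group means were 66.6% ± 11.5 (SD, n = 4) in control and 76.0% ± 2.01 (SD, n = 4) in R6/2 (exact permutation p = 0.114). The 75th percentile of the signal was 342 ± 8.13 intensity units in control and 358 ± 29.9 in R6/2 (SD, n = 4 each, exact permutation p = 0.371). Correlations between arrays, across probes, ranged from 0.925 to 0.963. R6/2 replicate 4 was alone on the second slide, so that slide and genotype cannot be compared within that slide, and the values within the first slide are those without this array.

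The series asks which genes of MSNs differ between R6/2 and control mice at this age. Genes that define MSNs were lower in R6/2. The log2 difference was -1.15 for the sodium channel subunit Scn4b, -1.84 for the ryanodine receptor Ryr1, -0.95 for the adenylate cyclase Adcy5, and -0.94 and -0.74 for the phosphodiesterases Pde10a and Pde1b. It was -0.90 for the cAMP-regulated phosphoprotein Arpp21 (with another of its 3 tested probes at -0.15), -0.88 and -0.76 for the dopamine receptors Drd2 and Drd1, and -0.74 for the opioid peptide gene Penk. In the MSN identity list, 29 of 30 tested genes had a negative difference, with a median of -0.64, and Hpca alone had a positive one (+0.02). None of the 30 passed over all genes tested, and 16 were lower adjusted over the list alone. Camera called the list lower at an adjusted p = 2.67e-20, and at an adjusted p = 0.0460 with an estimated correlation. The mean level of the list was 4.63 ± 0.12 in control and 4.01 ± 0.14 in R6/2 (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). It was lower in 4 of 4 R6/2 arrays than in any control array. The median difference within the first slide was -0.59. The exact test of this score and the value within the first slide were chosen after seeing the data.

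**Figure D1:**
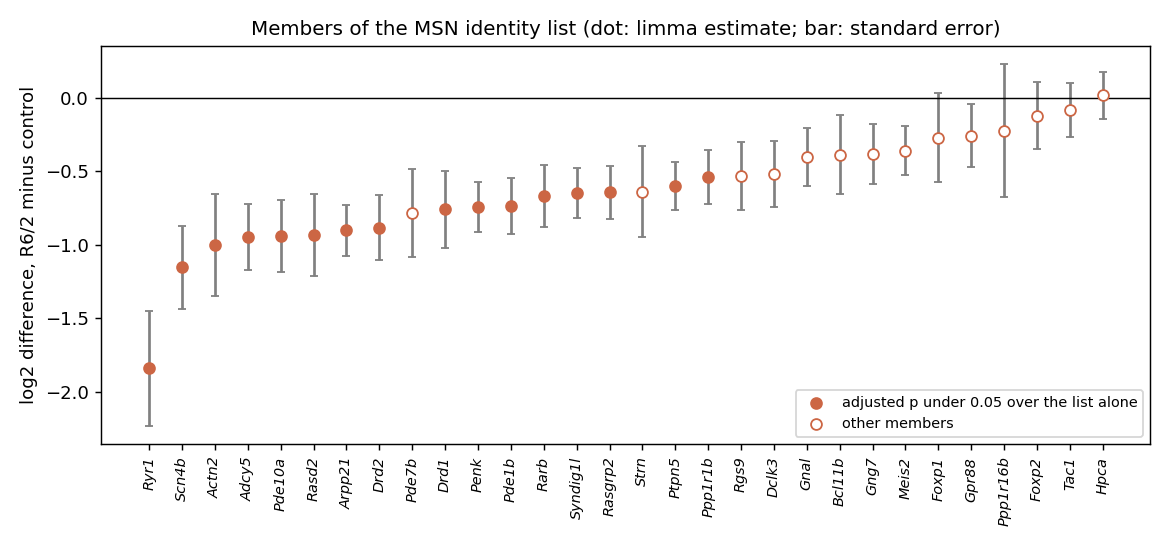
Log2 difference (R6/2 minus control, y axis) of each of the 30 tested genes of the MSN identity list (x axis), with the limma standard error as bars. Filled dots mark the 16 genes lower adjusted over the list alone, and 29 of 30 dots lie below 0.

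Genes reported lower in HD model striatum were also lower in sorted MSNs. Besides the genes they share with the MSN identity list, the list held the cannabinoid receptor Cnr1 (-1.18), the histamine receptor Hrh3 (-1.15), the inositol trisphosphate receptor Itpr1 (-0.85), the potassium channel partner Kcnip2 (-0.89), Strip2 (-0.81), the G protein regulator Rgs4 (-0.70) and Ddit4l (-2.47, with 1 of 4 R6/2 arrays well above background, so that its size depends on values near background). The growth factor gene Bdnf went the other way, at least 1.34-fold higher in R6/2, with 0 control arrays well above background. Of 40 tested genes, 37 had a negative difference and the median was -0.67. None passed over all genes tested, and 21 were lower and 1 was higher adjusted over the list alone. Camera gave an adjusted p = 3.28e-22 for this list, and an adjusted p = 0.0372 with an estimated correlation. It shares 18 genes with the MSN identity list. With shared genes left out of both lists, a test chosen after seeing the data, camera called both lower (adjusted p = 5.68e-05 for the 12 remaining MSN identity genes and 9.77e-09 for the 22 remaining genes), but not with an estimated correlation (adjusted p = 0.249 and 0.150).

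As lists, markers of both kinds of MSN were lower in R6/2 by camera with the preset correlation, but not with an estimated one. Among direct pathway (D1) genes, Cntnap3 (-1.80) and Asic4 (-0.68) were lower adjusted over the list alone, while Pdyn (-0.79) and Chrm4 (-0.77) did not pass. Among indirect pathway (D2) genes, Penk and Drd2 passed adjusted over the list alone, while Plxdc1 (-1.44, with its other probe at -0.07) and Sp9 (+0.65) did not. No gene of either list passed over all genes tested. The direct pathway list had a median of -0.30 over 15 genes, 11 negative and 4 positive (camera adjusted p = 0.00358, and adjusted p = 0.0935 with an estimated correlation). The indirect pathway list had a median of -0.44 over 15 genes, 14 negative and 1 positive (camera adjusted p = 2.86e-04, and adjusted p = 0.0935 with an estimated correlation). The indirect pathway score minus the direct pathway score was -0.73 ± 0.07 in control and -0.93 ± 0.17 in R6/2 (SD, n = 4 each). That difference of -0.20 did not pass (exact permutation p = 0.0857), so that an unequal shift of the 2 kinds of MSN was not shown. It reached p = 0.0286 in the same exact test with normexp background correction (-0.16) and without R6/2 replicate 3 (-0.26).

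**Figure D2:**
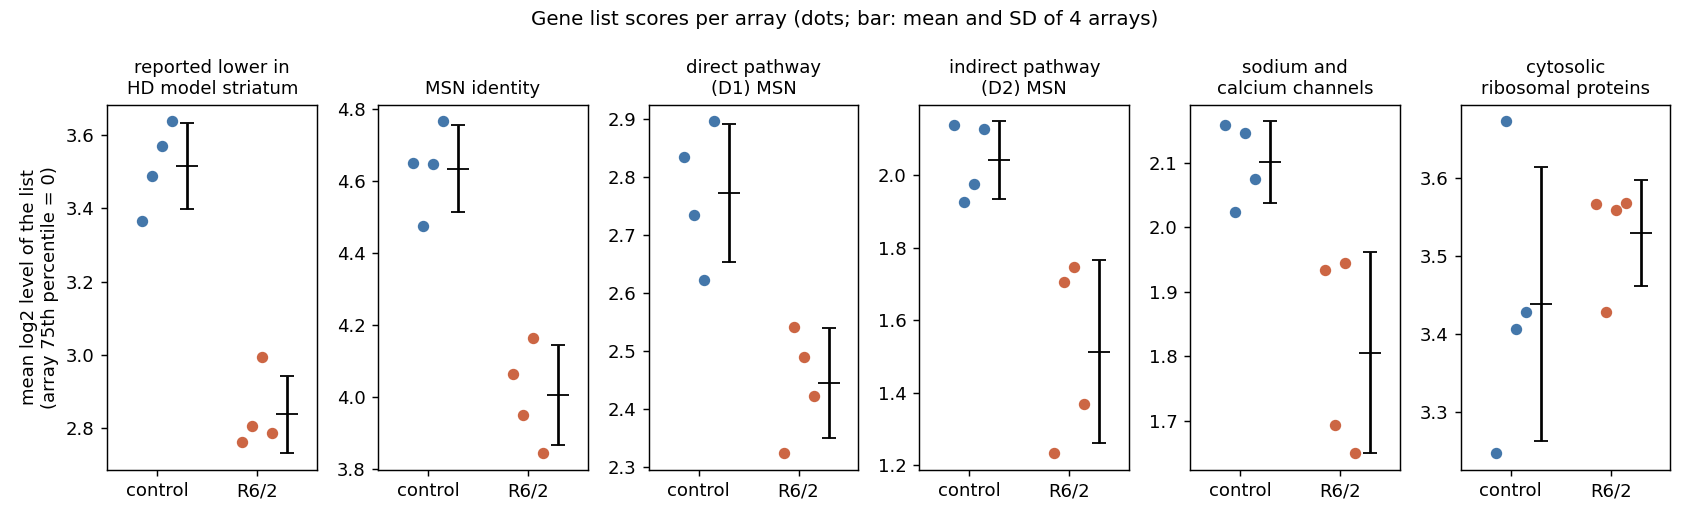
Mean log2 level of 6 gene lists on each array (y axis, array 75th percentile at 0), by genotype (x axis), with 4 dots per group and a bar for the mean and SD. All 4 R6/2 arrays lie below the 4 control arrays in the first 5 lists, and the groups overlap for cytosolic ribosomal proteins.

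Sodium and calcium channel, second messenger, glutamate receptor and retinoid genes were lower as groups. Of the sodium and calcium channels, Itpr1, Ryr1, the calcium channel subunit Cacna2d3 (-0.83) and Scn4b were lower adjusted over the list alone, and none over all genes tested. That list had a median of -0.29 over 36 genes (camera adjusted p = 5.43e-06, and adjusted p = 0.103 with an estimated correlation). In cAMP and phosphodiesterase signalling, Pde1c (-1.47, with 1 of its 3 tested probes at +0.66) stood beside Adcy5, Pde10a and Pde1b, with a list median of -0.33 over 37 genes (camera adjusted p = 5.43e-06, and adjusted p = 0.141 with an estimated correlation). In RGS and small G protein regulators, the smallest p-values were those of Rgs10 (-0.81), Rasgrp2 (-0.64), Rasd2 (-0.93) and Rgs4, with a list median of -0.31 over 26 genes (camera adjusted p = 3.77e-05, and adjusted p = 0.0935 with an estimated correlation). In glutamate receptors and postsynaptic density, Gria4 (-0.78), Grik5 (-0.66) and Grm5 (-0.48) were among the genes with the smallest p-values, with a list median of -0.26 over 41 genes (camera adjusted p = 4.19e-04, and adjusted p = 0.148 with an estimated correlation). In nuclear-receptor and retinoid signalling, these were Stra6 (-2.90, with 1 of 4 R6/2 arrays well above background), Rarb (-0.67), Rbp4 (-0.88) and Rxrg (-0.97), with a list median of -0.23 over 24 genes (camera adjusted p = 0.0385, and adjusted p = 0.295 with an estimated correlation). This last call held in 10 of 22 alternatives, and it was lost without control replicate 1, control replicate 2, R6/2 replicate 1 or R6/2 replicate 3, where its adjusted p rose as far as 0.144. In the lists of cAMP, RGS, glutamate receptor and retinoid genes, 0 genes passed in limma over all genes tested and 0 adjusted over the list alone. Camera thus called 9 lists lower and 0 higher, fry called 6 lower and 0 higher, and 2 lists stayed lower with an estimated correlation. These calls partly count the same genes: the cAMP list shares 7 with MSN identity and 4 with the genes reported lower. With such shared genes left out, a test chosen after seeing the data, camera called 8 lists lower, and 0 with an estimated correlation. The retinoid list then did not pass (camera adjusted p = 0.0897), and the cAMP list rose to an adjusted p = 0.0097. Of the 35 ways to split the 8 arrays into 4 and 4, the real one included, 4 gave at least 9 lists in 1 direction, and 1 gave at least 2 with an estimated correlation. Fry's mixed test, which takes changes in either direction, called 13 lists. Some of these were not called by camera. They were neuropeptides (fry mixed adjusted p = 7.17e-09), activity genes (0.0092), cholesterol synthesis (0.0172), regulators linked to huntingtin (0.0132), and progenitor and neuroblast markers (0.0132). Members of such lists can differ without a shared direction.

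The single transcript past the threshold over all genes was an unnamed one. Probe A_55_P2128060, on chromosome 4 of mm9 at 96388645 to 96388704, was at least 24.0-fold higher in R6/2 (adjusted p = 0.0142). Its log2 level was -6.28 ± 1.07 in control, with 0 of 4 arrays well above background, and 0.23 ± 0.26 in R6/2, with 4 of 4. It passed without control replicate 1 (adjusted p = 2.97e-04), and without any other single array its adjusted p ranged from 0.0631 to 0.120. The predicted gene Gm12695, whose probe lies 1933 bases further on, had a difference of +3.45 (adjusted p = 0.0704, higher in 4 of 4 R6/2 arrays), with 1 of 4 control arrays well above background. With normexp, whose offset of 50 lessens differences of dim probes, the differences were +2.82 for the former and +1.21 for the latter. In all, 1 of 26915 genes and transcripts changed, 1 higher and 0 lower. At an unadjusted p under 0.05 there were 996 higher and 928 lower, 1924 together against 1346 by chance, and the authors' kind of test on the same values gave 0 after adjustment and 1856 before. The groups did not overlap in 1273 genes (4.73% against 2.86% by chance), 581 higher and 692 lower.

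**Figure D3:**
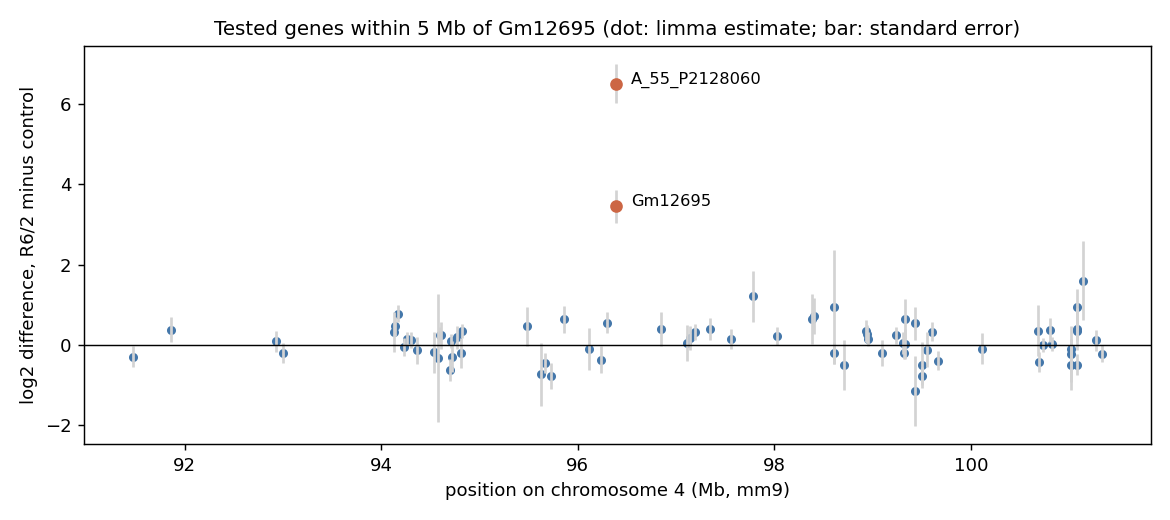
Log2 difference (R6/2 minus control, y axis) of the tested genes within 5 Mb of Gm12695, by position on chromosome 4 of mm9 (x axis, Mb), with the limma standard error as bars. A_55_P2128060 (+6.51) and Gm12695 (+3.45) stand above the 74 other genes, which lie between -1.15 and +1.59. The sizes of these 2 depend on control values near background, and for A_55_P2128060 the text gives a lower bound.

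At an adjusted p under 0.1 there were 10 transcripts, 8 higher and 2 lower. The growth factor gene Bmp2 was the annotated gene nearest the threshold, at -1.97 ± 0.19 (standard error, adjusted p = 0.0557), with 4 of 4 R6/2 arrays below every control array, and it passed in 6 of 20 alternatives. The prohormone convertase gene Pcsk1 was at least 2.94-fold higher (adjusted p = 0.0948), with 0 control arrays well above background. The others were the transcripts A230055C15 (-2.46), ENSMUST00000165619 (+1.69), LOC545005 (+1.71), Gm5796 (+1.65), Gm3727 (+1.53) and ENSMUST00000097320 (at least 3.08-fold higher), with Gm12695 and A_55_P2128060. ENSMUST00000165619, LOC545005, Gm5796 and Gm3727 lie on chromosome 14 of mm9 between 3076832 and 8330952. The tested transcripts there with a predicted, clone-type or unannotated name are here called the chromosome 14 family. They were picked by name and position and not by sequence, and genes with other names in the interval were left out. Of these 37 transcripts, 34 had a positive difference, with a median of +0.74. In limma 0 passed, while 20 were higher and 0 lower at an unadjusted p under 0.05. Of those 20 transcripts, 10 have a probe that shares 20 bases with another's.

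Among annotated genes with the smallest p-values, none passed over all genes. Fads3 (+2.25), Fancg (+1.35), Arl5a (+1.49), Bpnt1 (+1.05) and the noncoding RNA Snhg1 (+1.10) had positive differences at adjusted p-values up to 0.345. The other tested probe was at only +0.43 for Fads3 and +0.49 for Bpnt1. The titin gene Ttn and the histone gene H2bc23, with 0 control arrays well above background, were at least 4.35-fold and at least 3.03-fold higher (adjusted p = 0.219 and 0.250). Negative differences were seen for the plasminogen activator Plat (-2.13), Gpd1 (-1.90), Gsg1l (-1.04), Cnr1, Neto2 (-1.19), Tpst1 (-1.27) and Cpne9 (-1.62), at adjusted p-values from 0.244 to 0.345. Htt had a difference of +0.27 (adjusted p = 0.858). Its probe reads mouse Htt and does not check the human transgene.

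Neuropeptide, cholesterol, potassium channel, GABA, activity and protocadherin genes did not pass in camera as groups shifted in a single direction. Fry's mixed test did call the neuropeptide, cholesterol and activity lists. In neuropeptides and peptide receptors, Cnr1, the opioid receptor Oprk1 (-1.20) and Penk were lower adjusted over the list alone and none over all genes, and the list did not pass (median -0.08, adjusted p = 0.0744), though it was lower in 8 of 22 alternatives, among them those without control replicate 1 and without R6/2 replicate 4. For cholesterol synthesis, Hmgcs1 (-0.71) and Srebf2 (-0.70, with its other probe at +0.24) were among the genes with the smallest p-values, and the list did not pass (median -0.15, adjusted p = 0.0737), though it was lower in 3 of 22 alternatives, among them those without control replicate 2 and without control replicate 3. For potassium channels (median -0.09, adjusted p = 0.124), these were Kcnip2, Kcnj3 (+1.26, with its other probe at +0.12), Kcnk2 (-0.65) and Kcnj4 (-0.40). That list was lower in 2 of 22 alternatives, the mean of a gene's probes and without control replicate 2. For GABA receptors and GABA synthesis (median -0.10, adjusted p = 0.325), they were Gabrd (-0.63), Gabra4 (-0.46), Gad1 (-0.45) and Gabrg1 (+0.82). For immediate early and activity genes (median +0.07, adjusted p = 0.873), they were Bdnf, Inhba (-1.04), Fosb (+0.98) and Gadd45b (+1.503). For clustered protocadherins (median +0.11, adjusted p = 0.206), they were Pcdhb10 (+0.87), Pcdha4 (+1.11), Pcdhb4 (+1.76) and Pcdha8 (+0.61). In the other 5 of these 6 lists, 0 genes passed in limma over all genes tested and 0 adjusted over the list alone.

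Stress, energy and protein turnover genes showed no shift past the threshold. The smallest p-values belonged to Chordc1 (+0.96), Hspb1 (at least 2.73-fold higher), Hspa1l (+1.01) and Stip1 (+0.55) in chaperones and heat shock (median +0.03, adjusted p = 0.430), and to Calr (+0.75), Manf (+0.75), Ddit3 (-0.78) and Vldlr (-0.38) in the unfolded protein response (median +0.03, adjusted p = 0.967). In the proteasome (median +0.06, adjusted p = 0.873) they belonged to Psmd14 (+0.55), Psmd7 (+0.35), Psma4 (-0.30) and Psmc3 (-0.37), and in autophagy and lysosome (median +0.01, adjusted p = 0.978) among others to Wipi1 (-0.84), Gabarapl1 (-0.21) and Atg16l1 (+0.23). Oxidative phosphorylation (median -0.03, adjusted p = 0.914) was led by Ndufs7 (-0.40), Cox6a1 (+0.33), Cyc1 (+0.32) and Ndufs3 (-0.30), and glycolysis (median +0.00017, adjusted p = 0.873) by Slc2a3 (+0.70), Pgk1 (+0.35), Pdk1 (+0.43) and Pgam1 (+0.23). Cytosolic ribosomal proteins (median +0.11, adjusted p = 0.224) were led by Rps27 (+0.40), Rpl5 (+0.29), Rps9 (+0.27) and Rpl7a (+0.25, with 1 of its 4 tested probes at -0.01). In these 7 lists, 0 genes passed in limma over all genes tested and 0 adjusted over the list alone. The ribosomal list passed as higher with normexp, with quantile normalization, with probes above background on all 8 arrays and without control replicate 2.

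Nuclear and immune genes showed no list shift in a single direction either, though fry's mixed test called the regulators linked to huntingtin. In transcriptional and chromatin regulators linked to huntingtin (median +0.05, adjusted p = 0.967), the smallest p-values were those of Nfya (+2.22), Ezh1 (-0.99, with 2 of its 4 tested probes higher, up to +0.57), Kdm6a (+0.93) and Dnmt3b (+0.68, with its other probe at -0.19). In DNA mismatch and break repair (median +0.01, adjusted p = 0.792) they included those of Xrcc5 (+1.05), Parp1 (+1.31) and Rad50 (-0.46). In p53 targets and apoptosis (median +0.06, adjusted p = 0.792) they were those of Bcl2l1 (-0.60), Perp (-0.84), Sesn1 (-0.55) and Bbc3 (-0.99). In Polycomb-repressed developmental regulators (median +0.11, adjusted p = 0.430) they were those of Wnt10b (+1.63), Hand1 (+0.98), Hoxd11 (+0.52) and Hoxd3 (-0.38). In the interferon response (median +0.05, adjusted p = 0.562) they were those of B2m (+1.44), H2-D1 (+0.85), Irf7 (+0.50) and Oas2 (+0.40). In all 5 of these lists, 0 genes passed in limma over all genes tested and 0 adjusted over the list alone.

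No list of markers of other cell types passed in camera with the main settings. Oligodendrocyte markers had the most negative median (-0.90, camera adjusted p = 0.0543), with Mbp at -0.24, and the score of control replicate 2 stood at 1.48 against -1.45 to -0.27 in the other control arrays. That list was called lower in 10 of 22 alternatives: normexp, quantile normalization, no filter, the mean of a gene's probes, an intensity trend, the replicate block, the background share as a covariate, without control replicate 1, without control replicate 4, and without control replicate 1 and R6/2 replicate 4 together. Its adjusted p ranged from 0.00241 to 0.810 over the alternatives and was 0.607 without control replicate 2. Medians and camera adjusted p-values were +0.03 and 0.967 for astrocyte, +0.05 and 0.967 for oligodendrocyte precursor, +0.15 and 0.912 for microglia, and +0.01 and 0.967 for endothelial and mural markers. They were +0.06 and 0.967 for striatal interneuron, +0.08 and 0.985 for cortical glutamatergic neuron, +0.20 and 0.212 for progenitor and neuroblast, +0.13 and 0.658 for ependymal and choroid plexus, and -0.08 and 0.873 for erythrocyte markers. Each of the 10 scores had an exact permutation p adjusted to 0.971, in a design where the smallest exact p is 0.0286, too large for a single list to pass over 10. The doublecortin gene Dcx, a neuroblast marker, was higher (+1.18) adjusted over the list alone, and no marker passed over all genes tested. Astrocyte, oligodendrocyte precursor, striatal interneuron, cortical neuron and p53 target lists had a positive median with camera's direction lower, and oxidative phosphorylation had a negative median with a positive mean.

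The authors' table and these fits rest on the same 8 arrays. The authors' smallest corrected p-value, 0.0998, was shared by 7 probes, among them those of Bmp2, ENSMUST00000165619, LOC545005, Gm5796 and Gm3727, and A_55_P2128060 had 0.125, so that 0 of 55680 probes passed in that table, against 3179 at an unadjusted p under 0.05. Across 26915 genes, which are not independent replicates, the authors' log2 fold changes and those of limma correlated at 0.995 and had the same sign in 99.7%. Of the 100 genes with the smallest p-value in each, 47 were shared, against 0.372 by chance. They differed by over 0.1 in 41 genes, by up to 3.11.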

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

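The tests of other cell types, of the slide, of probes near background, of copies and of a strain segment of the chromosome 4 region, and the counts of splits with an estimated correlation and at an unadjusted p were chosen after the result was seen. The chromosome 14 family was picked after its values were seen, so that its tests were chosen after the data were examined as well.

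The oligodendrocyte score of R6/2 replicate 2 was -1.87, far below the -0.98 to -0.87 of the other R6/2 arrays, as the mean over 12 marker genes. The ribosomal protein score of the same array was 3.43, against 3.56 to 3.57. In R6/2 replicate 4, the neuropeptide score was 0.14, against -0.44 to -0.37, and the cholesterol synthesis score was 0.49, against 0.28 to 0.31. In all, 4 of 140 groups of arrays had an array this far from the others, and chance alone gives about 7. No biological explanation was tested for single arrays.

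The MSN identity list, with Ryr1, Scn4b, Adcy5 and Pde10a, was lower in R6/2, and 29 of its 30 genes had a negative difference. More RNA of other cell types in the R6/2 samples would raise those cells' genes as the MSN genes fall, yet 97 markers of other cell types, 57 of them above background on all 8 arrays, differed by -0.011 on average (standard error 0.23), below the 0.64 by which the MSN list fell. That mean pools oligodendrocyte markers, which averaged -0.77, with the other marker lists, which averaged from -0.11 to +0.21. The pooled mean leans on control replicate 2, whose markers stood highest, and was +0.19 (standard error 0.16) without it. Without control replicate 3 it was +0.02, but 2 standard errors above it (0.66) exceeded the fall of 0.61. With all arrays, the pooled mean argues against such RNA as the whole cause, but without control replicate 3 it does not. With the markers' score as a covariate, the MSN identity score differed by -0.63 (standard error 0.08), and by -0.68 to -0.58 without 1 array. Because the pooled markers hardly differed between the groups, this covariate could hardly move the MSN difference, and it adds little. A sort on Venus and propidium iodide is meant to remove such cells. Brighter probes reading lower whatever the gene is argued against by 10000 random lists matched on brightness, whose lowest median was -0.24. The slide of R6/2 replicate 4 is argued against as well, since the median was -0.59 within the first slide, where the 3 R6/2 scores lay below every control score. A lower expression of MSN genes in R6/2 neurons and a different mix of MSNs entering a sort that itself reports Scn4b both stay open, and no value here decides between them.

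The unnamed probe A_55_P2128060 and the predicted gene Gm12695, 1933 bases apart on chromosome 4, were higher in R6/2, though Gm12695 did not pass. Noise of probes near background would leave a small fold, and the lower bound of the fold was 24.0. With normexp, whose offset narrows it, the log2 difference was +2.82, still above 2-fold. More copies of the whole surrounding region would raise its genes by 0.58, and the 74 other tested genes within 5 Mb had a median of 0.106, with an upper 95% bound of 0.23. A segment of another strain over these 5 Mb would shift its other genes as well, and 5.41% of the 74 had an unadjusted p under 0.05, against 7.15% of all genes, with an upper bound of 13.27%, which argues against a segment that doubles that share. A local event, such as the place where the transgene sits in R6/2 mice or a strain variant of the locus alone, may explain the pair, and neither was tested.

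ENSMUST00000165619, LOC545005, Gm5796, Gm3727 and most other transcripts of the chromosome 14 family, a set picked by name and position, had positive differences in R6/2. None passed with the main settings, while ENSMUST00000165619 and LOC545005 passed in 6 of 20 alternatives and Gm5796 and Gm3727 in 5. If their probes read the same transcripts, the members would rise and fall together within groups. The deviations of the 37 family transcripts from their group means had a mean correlation of 0.0739. That is above 95% of 1000 random sets of the same size and brightness (0.0660) but below the highest (0.182), which does not decide it. This mean also covers transcripts with hardly any difference, and the named ones were not tested alone. In each of the named ones, R6/2 replicate 4 stood highest of the R6/2 arrays (log2 levels of 3.00, 2.59, 1.85 and 2.01). The lowest control array was not the same in all of them. A segment of another strain around the family would also shift neighbouring genes, and of 13 named genes up to 5 Mb beyond it 7.69% had an unadjusted p under 0.05, against 7.15% of all genes, with an upper bound of 36.03%. Shared probe sequence, a strain segment and an R6/2 effect on the family cannot be told apart, because the neighbours are few and the probes of some members overlap.

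Chance can be set against each count through the 35 ways to split the 8 arrays into 4 and 4. For the single gene past the threshold, 2 splits gave at least 1 gene, and the highest other split gave 1, so that chance is not excluded. For the 9 lists lower by camera, 4 splits gave at least 9 lists in 1 direction and the highest other split gave 10, so that chance is not excluded for this count. For the 2 lists lower with an estimated correlation, 1 split, the real one, gave as many and the highest other gave 0. That is the smallest share possible, for a count chosen after the 9 lists were seen. The 2 lists share 18 genes, so that this count does not firmly exclude chance. For the 1924 genes at an unadjusted p under 0.05, 1 split, the real one, gave as many, the smallest share possible, but the highest other gave 1866, so close that this count, chosen after those above, does little to exclude chance.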

How the results depend on the processing

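The authors' kind of test, the lists without shared members, and leaving out control replicate 1 with R6/2 replicate 4 were chosen after seeing the data.

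The genes reported lower in HD model striatum and the MSN identity genes kept their direction and passed in 22 of 22 alternatives, with medians from -0.77 to -0.60 and from -0.74 to -0.55. The count of 9 lower lists was 2 with an estimated correlation, whose construction widens the test, and 6 to 12 otherwise. The 6 with the share of probes well above background as a covariate held 4 of the 9: the direct and indirect pathway, channel, glutamate and retinoid lists did not pass (adjusted p = 0.0803, 0.0775, 0.0652, 0.245 and 0.0775). In that order, their medians with the covariate were -0.22, -0.26, -0.16, -0.25 and -0.31. With the main settings they were -0.30, -0.44, -0.29, -0.26 and -0.23. Without control replicate 1 and R6/2 replicate 4, 6 of the 9 passed, and the direct pathway, glutamate and retinoid lists did not (0.0964, 0.294 and 0.0775). Over all alternatives the highest adjusted p was 0.0964 for the direct pathway, 0.0935 for the indirect pathway and RGS, 0.103 for channels, 0.141 for cAMP, 0.294 for glutamate and 0.295 for retinoid genes, which passed in 10 of 22. For these 9 lists, 26 values no longer passed and 172 kept their side. Lists not called were lower in 23 values (oligodendrocyte 10, neuropeptides 8, cholesterol 3, potassium channels 2) and higher in 6.

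The count of 1 changed gene, 1 higher and 0 lower, moved with the processing, and the cause was not tested. It was 8 with normexp (6 higher, 2 lower), 8 with quantile normalization (6 higher, 2 lower), 6 with probes above background on all 8 arrays (4 higher, 2 lower), 5 with the mean of a gene's probes (4 higher, 1 lower), 11 with an intensity trend (7 higher, 4 lower), and 9 with array weights (7 higher, 2 lower). It was 2 (2 higher) with the background share as a covariate, 10 at an adjusted p under 0.1 (8 higher, 2 lower), and 0 (0 higher) by the authors' kind of test, where 1856 had an unadjusted p under 0.05. Median scaling, no filter, every probe on its own, the authors' values and a 2-fold limit gave 1. Among named genes, 2383 values stayed on their side of the threshold, 41 passed only under an alternative, 8 no longer passed, all of them of A_55_P2128060, and 2 changed sign without passing (Hoxd11 and Pdk1).

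Without 1 array, the count ranged from 0 to 3 changed genes (0 to 3 higher): 3 without control replicate 1, and 0 without any other array. Without control replicate 1 and R6/2 replicate 4 it was 3 (3 higher). The count of higher lists, 0, ranged from 0 to 1 without 1 array: 1 without control replicate 2 (ribosomal proteins). It was 1 with normexp and 1 with probes above background on all 8 arrays (ribosomal proteins), 2 with quantile normalization (ribosomal proteins and chaperones), and 1 without control replicate 1 and R6/2 replicate 4 (protocadherins). The cause was not tested. No result past the threshold reversed.

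The indirect minus direct pathway score, -0.20, was -0.16 with normexp and ranged from -0.26 to -0.15 without 1 array, with -0.26 without R6/2 replicate 3. These 2 passed (exact permutation p = 0.0286, the smallest possible in each), and the exact p ranged up to 0.286 over the alternatives. The cause was not tested.

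With the replicate block, limma called 0 genes (0 higher), with 1833 at an unadjusted p under 0.05, and 10 lists lower, the main 9 among them. The labels do not say that equal numbers share a litter or day. Deviations of arrays with the same number correlated at 0.03, -0.05, 0.003 and -0.006. Only the arrays of replicate 1 were each other's best partner across genotypes. These values show no clear pairing by number, but so few correlations cannot exclude a shared litter or day.

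Signal over background limits Bdnf, Pcsk1, Ttn, H2bc23 and other genes at background in every control array, whose folds are lower bounds, and Stra6, Ddit4l, Gm12695, Pcdha4 and Oas2, above it on 1 array of a group. With normexp, whose offset narrows dim differences by construction, A_55_P2128060 (+2.82), Pcsk1 (+0.70), Ttn (+1.12), H2bc23 (+0.74), Bdnf (+0.20), Hspb1 (+0.52) and ENSMUST00000097320 (+0.74) lay under their bounds.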

Other observations

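All values here were singled out after they were seen. Mpzl3, a neighbour of Scn4b on chromosome 9 whose probe lies at 44882887 to 44882946 on mm9, had a log2 difference of -2.12, with 4 of 4 R6/2 arrays below every control array (limma, adjusted p = 0.392). The groups lay apart in this way in 692 genes, and an effect on the region around Scn4b was not tested.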
